A study of Lates calcarifer with 22 samples.

How the data were processed

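Gonad RNA from 22 Asian seabass samples was measured on single-colour Agilent arrays of custom design, 1 array per sample. Per the file headers, the arrays were extracted with Agilent Feature Extraction 10.7.1.1, and the processed signal is a spot intensity that was background-subtracted and corrected for spatial trend within the array, with no normalization between arrays. The deposited files also hold the median pixel intensity of each spot and of its local background, and marks for spots well above background, saturated or out of line with their own pixels or replicate spots. The authors' series matrix holds log2 values. Its sorted columns differ by at most 0.0014, as after quantile normalization, each column has a median of 4.50, and each correlates at 0.993 or more with the log2 scanner signal of the same array, so its scale and direction are known and no centring of genes was seen. The steps behind it are not given in the sources used here beyond Partek, which is named per the submitters' processing notes. All 22 columns of the matrix were matched to samples by name.

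Samples were grouped by the stage and age in the labels. Each array had 62899 spots, of which 1319 control spots were left out, and 60080 probes, of which 300 had 6 spots each. The 2576 spots that the scanner software marked as outliers were left out, counted over all arrays, and spots of 1 probe were averaged on the log2 scale. The 2 saturated values were kept. Values were log2 of the processed signal minus the 75th percentile of the array. A probe was tested if it was well above background on every array of at least 1 group, which kept 35868 probes. A probe with several spots counted as above background where a share of at least 0.5 of its spots was.

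Differences were tested per probe with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), and files were read with the package data.table (version 1.17.8). All 22 arrays were fitted together without covariates, so that the groups of 3 and 4 shared 1 estimate of the spread, and each of the 6 comparisons was a contrast of that fit. A probe was called where the p adjusted by Benjamini-Hochberg within the comparison was under 0.05. Sex classes were the probes called between adult ovary and adult testis with at least a 2-fold difference. For the comparisons that include adult arrays, the classes were found again with adult replicates 1 and 2 and compared using replicates 3 and 4, and the reverse, so that no adult array served both purposes. Positions between the adult means were compared by exact two-sided permutation tests. Each adult array was placed with classes and means found without it.

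The calculations were tested on simulated data with the real arrays' spread, in which 100 probes were changed by 2-fold and 100 by 4-fold among 35868. For adult ovary against adult testis 3% of the 2-fold and 38% of the 4-fold changes were recovered, with 3 false calls. For late against early transforming gonads 4% and 42% were recovered with 2 false calls, for early transforming gonads against adult testis 4% and 25% with 2, and for adult ovary against late transforming gonads 1% and 36% with 4. For early testis against undifferentiated gonads 0% and 27% were recovered with 1 false call, and for adult testis against early testis 1% and 35% with 3. When few probes change, most 2-fold changes would thus be missed, and the share missed depends on how many change together.

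The rule for naming genes, fixed before the data were examined, took the called genes with the largest rises and falls whose groups did not overlap, the members of fixed gene lists and a set of known sex genes, and gave probes by identifier where no gene is named. None of the 60080 transcript identifiers matched the reference gene table of assembly TLL_Latcal_v3, which lists 32906 genes, so no gene was named and the gene list tests were not run. The 2 probes with the largest fitted rise and the 2 with the largest fitted fall between adult ovary and adult testis are given by identifier. Fitted folds of probes near background have no reliable order. For SBRGG_01719, SBRGG_39226 and SBRGG_29268 the fold is therefore given against a floor, the lowest signal well above background. SBRGG_11790 was well above background on 3 adult testis arrays but not on all of them, and its fitted fold is given.

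The arrays lay on 3 slides of the same scan day, with every group on all 3 except early testis, which was on slides 1 and 3. Alternatives fixed before the data were examined were scaling to the median, quantile normalization, normexp background correction with an offset of 50, other filters on dim probes, saturated and outlier spots, the authors' matrix values, the slide as a block, fits of the compared groups only, no intensity trend, a 2-fold threshold and leaving out each array. The mean spot signal planned for normexp was not used here, and the median spot signal took its place. Leaving out each slide in turn, the division of the adult replicates and the count of probes above background per array were chosen after the data were seen.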

Results

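Gene expression was measured in the gonads of Asian seabass (Lates calcarifer), a protandrous fish in which most individuals mature as males and later change into females. The 22 samples fell into 6 groups that follow this life course. Undifferentiated gonads came from juveniles of 4.5 months (n = 4), and early testes at stage M3 from fish of 8 and 9 months (n = 3). Adult testes at stage M3 (n = 4) and adult ovaries at stage F3 (n = 4) came from fish of 5 years. Early transforming gonads at stages T1/T2 (n = 3) and late transforming gonads at stages T3/T4 (n = 4) came from fish older than 2 years. The labels name the samples separately but say no more about how they were taken, so p-values measure the spread between these samples. Each sample was hybridised to 1 single-colour array carrying 60080 probes, each for a different transcript. The share of probes well above background ranged from 40.7% in adult ovary replicate 4 to 59.7% in early testis replicate 3, and the number of arrays limits the precision. The files pair the probes with transcript identifiers and no gene names, so results are given for classes of transcripts defined by the adult sexes, and only 4 transcripts are named by identifier.

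Adult ovary and adult testis differed in most of the probes tested. Of the 35868 probes that passed the filter on dim signal, out of 60080, 12235 were higher in ovary and 11135 were higher in testis, together 65.2% of those tested. With median scaling these counts were 13558 and 9887, and after quantile normalization 11092 and 11124, so which direction held more calls depended on the scaling. Among the called probes that were well above background on every adult array, the 8541 higher in ovary had a median fold of 4.61 (quartiles 2.78 and 9.03) and the 3465 lower in ovary had a median fold of 4.34 (quartiles 2.66 and 8.52). Transcripts marked as detected in 1 sex alone lay mostly on the testis side. A total of 4547 called probes were well above background on all 4 testis arrays and on no ovary array, against 688 with the opposite pattern. The ovary arrays were also dimmer, with a 75th percentile signal of 97.2 to 128.7 against 135.0 to 172.4 on the testis arrays, and fewer of their probes were well above background (43.2% against 55.9%), so these 2 counts can depend on array brightness. Calls were made with limma at a Benjamini-Hochberg adjusted p under 0.05. The median standard error of the log2 fold was 0.45 over the called probes. With the slide as a block the count was 23021. To test the sign on arrays that took no part in the calls, each slide was left out in turn, and on slides 1, 2 and 3 the difference had the same sign in 97.3%, 98.1% and 98.8% of the probes called on the other slides, where chance gives 50%.

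The 4 named transcripts spanned the extremes of the adult difference. SBRGG_11790 stood at a log2 level of 10.81 ± 0.81 (SD, n = 4) in adult ovary and -1.23 ± 1.47 (SD, n = 3, since 1 spot was left out as an outlier) in adult testis, a log2 fold of 12.04 with a standard error of 1.16 (limma, adjusted p = 2.26e-08). That spot lay on adult testis replicate 4. With it kept the log2 fold was 10.17, and in the authors' series matrix values 9.70. SBRGG_11790 was well above background on 3 of the 4 adult testis arrays. SBRGG_01719 stood at 10.02 ± 0.19 (SD, n = 4) in ovary and -1.36 ± 4.50 (SD, n = 4) in testis, where it was well above background on 2 of the 4 arrays. Against the floor explained below, ovary was 1792.8-fold higher (limma, adjusted p = 6.14e-07). The same adult testis replicate 4 alone reached 5.12 for SBRGG_01719, and the fitted log2 fold was 11.38 with this array and 13.54 without it. SBRGG_39226 stood at 10.19 ± 0.11 (SD, n = 4) in testis and was not well above background on any ovary array. Against the floor, testis was 7322.9-fold higher (limma, adjusted p = 1.15e-07). SBRGG_29268 stood at 10.60 ± 0.64 (SD, n = 4) in testis and was likewise not well above background in ovary. Against the floor, testis was 9693.4-fold higher (limma, adjusted p = 5.84e-08). These 3 folds set the mean of the bright group against the lowest signal well above background on each array of the dim group, or the dim probe's own signal where that was higher. They are not lower bounds under all processing. With normexp the fitted log2 folds, ovary minus testis, were smaller in size, at 9.31 for SBRGG_01719, -11.37 for SBRGG_39226 and -11.66 for SBRGG_29268. In adult testis replicate 1 SBRGG_29268 lay at 9.64, below the other adult testes.

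The same transcripts traced the life course. SBRGG_29268 was at -1.17 ± 4.42 (SD, n = 4) in undifferentiated gonads, where 2 of 4 arrays were well above background, and at 10.83 ± 0.28 (SD, n = 3) in early testis. It stood at 4.97 ± 4.61 (SD, n = 3) in early transforming gonads and -2.10 ± 0.29 (SD, n = 4) in late transforming gonads. SBRGG_39226 was at 10.11 ± 0.21 (SD, n = 2) in early testis, with 1 spot left out as an outlier, and at 3.46 ± 5.18 (SD, n = 3) in early transforming gonads. It was not well above background on any late transforming array. SBRGG_11790 was not well above background in any undifferentiated gonad, stood at 2.08 ± 3.64 (SD, n = 3) in early transforming gonads and reached 10.43 ± 0.92 (SD, n = 4) in late transforming gonads. SBRGG_01719 stood at 0.84 ± 2.37 (SD, n = 3) in early transforming gonads and 8.35 ± 1.18 (SD, n = 4) in late transforming gonads, where replicate 2 was the lowest at 6.60. The spread among the 3 early transforming gonads was wide for all 4 transcripts, with SBRGG_29268 between 1.43 and 10.19.

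**Figure D1:**
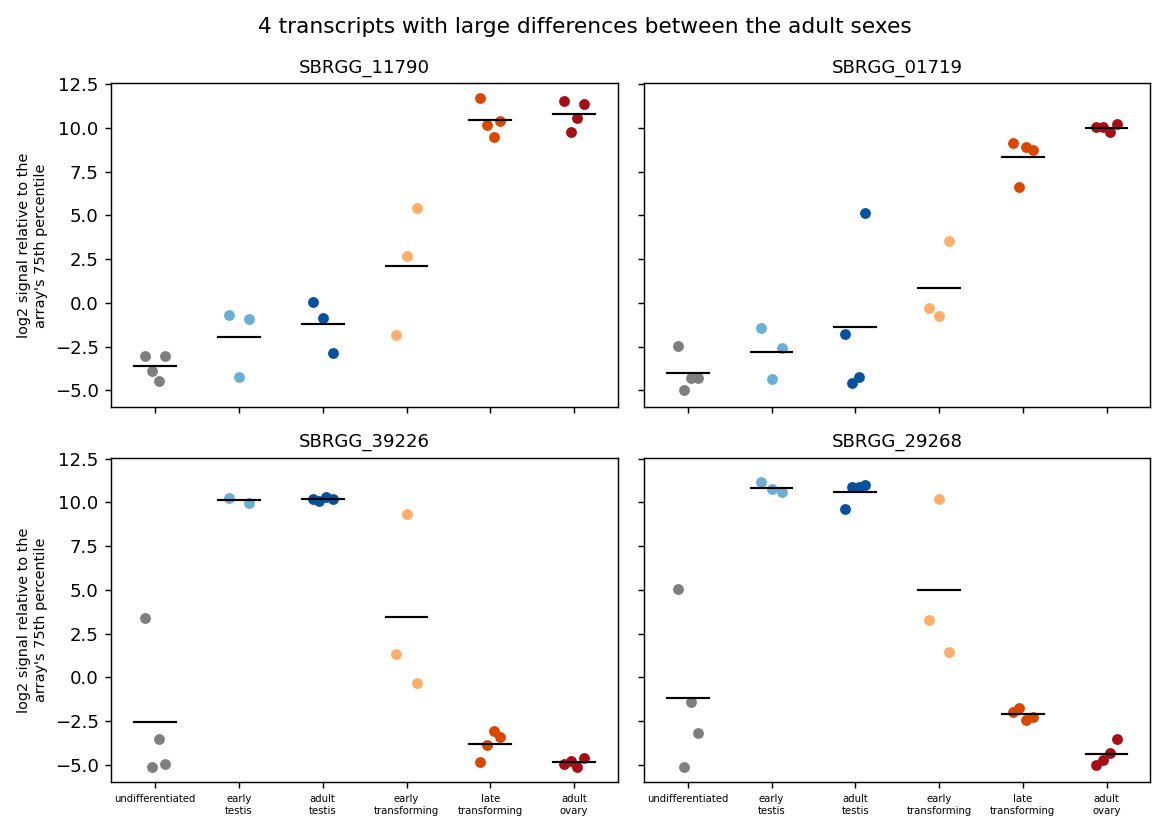
Log2 signal relative to the 75th percentile of the array (vertical axis) of 4 transcripts in the 6 groups (horizontal axis); each point is 1 array and each line the group mean. SBRGG_11790 and SBRGG_01719 are high in late transforming gonads and adult ovary, SBRGG_39226 and SBRGG_29268 in early and adult testis, and the early transforming gonads are widely spread, with SBRGG_29268 from 1.43 to 10.19 and all 3 values of SBRGG_01719 inside the adult testis range; levels of different probes are not comparable.

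The first male differentiation was followed by comparing early testis with undifferentiated gonads. Early testis was higher in 7309 probes and lower in 7420, together 41.1% of those tested. The transcripts that are at least 2-fold higher in adult testis than in adult ovary took the larger share of the higher calls. Of these 10802 testis-higher probes, 4336 were higher in early testis and 1521 lower. Of the 11557 ovary-higher probes, 1191 were higher and 2445 lower. This fall was not particular to ovary-higher probes. Of the 13509 probes in neither sex class, 1782 were higher and 3454 lower. That is 25.6% lower against 21.2% of the ovary-higher probes, with median log2 folds of -0.446 and -0.300. A total of 1718 called probes were well above background on all early testis arrays and on no undifferentiated array, against 144 with the opposite pattern. The undifferentiated arrays were also dimmer, with a 75th percentile signal of 92.2 to 147.6 against 166.5 to 203.2 on the early testis arrays, and fewer of their probes were well above background (49.2% against 57.3%), so these 2 counts can depend on array brightness as well. Among called probes well above background on every array of both groups, the 2875 higher ones had a median fold of 3.45 and the 5309 lower ones a median fold of 3.32. Calls were made with limma as above. The slide block gave 14885 calls, and on slides 1 and 3, which held both groups, the sign was the same in 95.3% and 94.3% of the probes called on the other slides. The share of calls higher in early testis was 49.6%, but 59.2% with median scaling and 51.6% after quantile normalization, so which direction held more calls depended on the scaling. The groups also differ in age by design.

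Early and adult testis, both at stage M3, had the fewest calls of the 6 comparisons in the fit of all groups. With normexp (8448 against 8023) or with only the compared groups in the fit (10485 against 9260), adult ovary against late transforming gonads had fewer. Adult testis was higher in 3741 probes and lower in 3456, together 20.1% of those tested. Of the called probes, 203 were well above background on all adult testis arrays and on no early testis array, and 568 had the opposite pattern. These 2 counts can depend on array brightness. Among probes well above background throughout both groups, the 2785 higher ones had a median fold of 2.81 and the 1749 lower ones a median fold of 3.22. Testis-higher transcripts tended to stand higher in the adults. With the sex classes taken from adult replicates 1 and 2 and the comparison from adult testis replicates 3 and 4, 111 testis-higher probes were higher and 32 lower, while 15 ovary-higher probes were higher and 220 lower. With the replicates exchanged, these counts were 1001 and 169 for testis-higher and 105 and 897 for ovary-higher probes. The limma count fell to 3229 without early testis replicate 3, 4097 without adult testis replicate 2 and 4645 without early testis replicate 1, and to 6339 with the slide as a block, while on slides 1 and 3 the sign was the same in 84.7% and 90.6% of the probes called on the other slides. The share of calls higher in adult testis was 52.0%, and 40.0% after quantile normalization or 39.6% in the authors' series matrix values, so which direction held more calls depended on the scaling.

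The start of the sex change was followed by comparing early transforming gonads with adult testis. Early transforming gonads were higher in 8739 probes and lower in 8759, together 48.8% of those tested, and with median scaling higher in 7348 and lower in 9750. The decrease was concentrated in testis-higher transcripts. With the classes taken from adult replicates 1 and 2 and adult testis replicates 3 and 4 used for the comparison, 4036 of 8791 testis-higher probes were lower and 428 higher, and 2113 of 9702 ovary-higher probes were higher and 387 lower. With the replicates exchanged, 4189 of 7859 testis-higher probes were lower and 2889 of 9028 ovary-higher probes were higher. Of probes well above background throughout both groups, the 4951 lower ones had a median fold of 4.42 and the 4930 higher ones a median fold of 3.63. A total of 1362 called probes were well above background on all adult testis arrays and on no early transforming array, and 686 showed the opposite. Such counts can depend on array brightness. In limma the slide block gave 17538 calls, and on slides 1, 2 and 3 the sign was the same in 92.3%, 98.7% and 92.6% of the probes called on the other slides. The age of the transforming fish is given only as over 2 years, against 5 years for the adult testes.

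Between early and late transforming gonads, ovary-higher transcripts increased and testis-higher transcripts decreased. Late transforming gonads were higher in 9928 probes and lower in 9514, together 54.2% of those tested. With median scaling 11001 were higher and 7567 lower, and after quantile normalization 8707 and 9665, so which direction held more calls depended on the scaling. Of the 11557 ovary-higher probes 6850 were higher in late transforming gonads and 715 lower, with a median log2 fold of 1.53. Of the 10802 testis-higher probes 5238 were lower and 631 higher, with a median log2 fold of -1.24. Among probes called both here and between the adult sexes, 12504 changed in the direction of adult ovary and 1521 in the opposite direction, so that 89.2% went the same way. Lists drawn independently would share 3387 probes higher and 2954 probes lower in both comparisons, against 7142 and 5362 observed. No array entered both comparisons. The correlation of the 2 sets of log2 folds was r = 0.62 across probes, which are not independent replicates. Probes called and well above background throughout both groups had a median fold of 4.24 where higher (6793 probes) and 3.35 where lower (3667 probes). In limma the slide block gave 19293 calls, and on slides 1, 2 and 3 the sign was the same in 96.8%, 93.3% and 93.4% of the probes called on the other slides.

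Late transforming gonads were close to adult ovary, although 25.2% of the tested probes still differed. Adult ovary was higher in 4932 probes and lower in 4102. The differences continued in the direction of the sex classes. With the classes taken from adult replicates 1 and 2 and adult ovary replicates 3 and 4 used for the comparison, 1357 of 9702 ovary-higher probes were higher in adult ovary and 193 lower, while 877 of 8791 testis-higher probes were lower and 158 higher. With the replicates exchanged, 1707 ovary-higher probes were higher and 1009 testis-higher probes lower. Of the called probes, 599 were well above background on all late transforming arrays and on no adult ovary array, and 145 showed the opposite. The 75th percentile signal was 97.2 to 128.7 on the adult ovary arrays against 121.7 to 194.4 on the late transforming arrays. Fewer adult ovary probes were well above background (43.2% against 49.5%), so these 2 counts can depend on array brightness. Median folds were 2.86 for the 3576 higher and 3.17 for the 1390 lower probes that were well above background throughout both groups. In limma the slide block gave 9165 calls, and on slides 1, 2 and 3 the sign was the same in 88.7%, 94.9% and 97.4% of the probes called on the other slides. The share of calls higher in adult ovary was 54.6%, but 67.4% with scaling to the median of each array and 49.95% after quantile normalization.

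**Figure D2:**
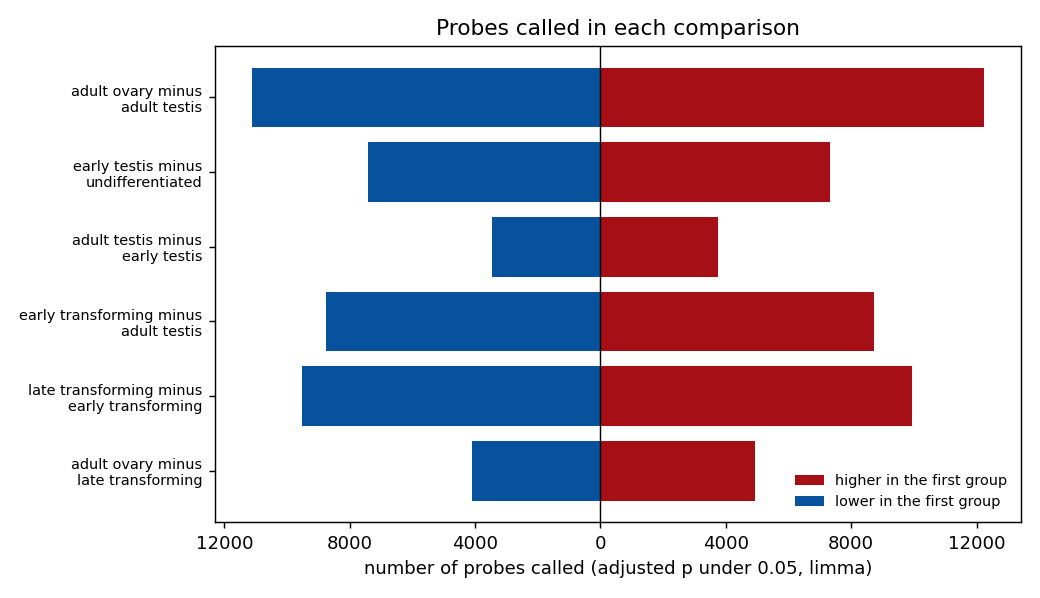
Number of probes called with limma at an adjusted p under 0.05 (horizontal axis) in each of the 6 comparisons (vertical axis), with probes higher in the first group to the right of 0 and probes lower to the left. Adult ovary against adult testis has the longest bars, with 12235 higher and 11135 lower, and adult testis against early testis the shortest in this fit, with 3741 and 3456.

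Each gonad was then placed between adult testis (0) and adult ovary (1), by the median over the sex-class probes of its position between the adult means. Undifferentiated gonads stood at 0.302 ± 0.0126 (SD, n = 4), early testis at 0.138 ± 0.0287 (SD, n = 3) and adult testis at 0.0082 ± 0.0665 (SD, n = 4, each adult placed without itself). Early transforming gonads stood at 0.320 ± 0.0624 (SD, n = 3), late transforming gonads at 0.832 ± 0.102 (SD, n = 4) and adult ovary at 0.995 ± 0.0243 (SD, n = 4). The largest step was from early to late transforming gonads, a difference of 0.512. The steps from adult testis to early transforming (0.312), from late transforming to adult ovary (0.163) and from undifferentiated gonads to early testis (-0.164) were smaller. In each of these 4 steps every array of one group lay beyond every array of the other, and the exact two-sided permutation test gave p = 0.0286, the smallest p possible, with an adjusted p of 0.0357 over 5 tests. With normexp background correction the step from late transforming gonads to adult ovary was 0.0986 and missed the threshold (exact permutation test, adjusted p = 0.0714). It also missed the threshold without any 1 of the 4 adult ovary arrays (exact permutation test, adjusted p = 0.0571 each time). The step from early to adult testis (-0.130) had p = 0.0571 and adjusted p = 0.0571 by the same exact permutation test, which compares means. Its arrays did not overlap either, with adult testis at most 0.0925 and early testis at least 0.1085. The directions held within every slide that had both groups, where the difference ran from 0.412 to 0.644 for late against early transforming, from 0.196 to 0.363 for early transforming against adult testis and from 0.0788 to 0.326 for adult ovary against late transforming. Within slides the early testis step was -0.169 and -0.165, and the adult testis step -0.0447 and -0.111.

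In early transforming gonads the testis-higher probes stood at 0.475 ± 0.107 (SD, n = 3) and the ovary-higher probes at 0.229 ± 0.0409 (SD, n = 3). Replicate 3 (0.599 and 0.274), whose label is examined below, lay above replicates 1 (0.414 and 0.218) and 2 (0.412 and 0.1945). In late transforming gonads both classes were close together, at 0.852 ± 0.0827 (SD, n = 4) and 0.818 ± 0.117 (SD, n = 4). The gap of testis-higher over ovary-higher probes was positive in all 3 early transforming gonads. It exceeded that of adult testis by 0.254 and that of late transforming gonads by 0.212 (exact two-sided permutation test, p = 0.0286 for each, unadjusted and the smallest possible). Adult testis sets the origin of both positions, so its gap (-0.008) is small by construction. The test against it therefore asks only whether early transforming gonads have a gap. Adult ovary sets the value of 1 for both positions, and its gap (-0.0046) is small for the same reason. Late transforming gonads stood near that end, which can narrow their gap, so the test against them is limited too. The size of the early transforming gap depended on the scaling and on the probes. It had a mean of 0.246, but 0.460 with median scaling, 0.168 after quantile normalization and 0.163 in the authors' series matrix values. On probes well above background on all 8 adult arrays it was 0.526, and 0.778 with median scaling. Under each of the 3 other scalings of all sex-class probes, added after the data were seen, the exact permutation tests against adult testis and late transforming gonads again gave p = 0.0286. Quantile normalization and the authors' matrix gave nearly the same gap and are not separate checks. Undifferentiated gonads had a wider mean gap in the main scaling, with testis-higher probes at 0.550 ± 0.0594 (SD, n = 4) and ovary-higher probes at 0.172 ± 0.0128 (SD, n = 4). Early testis had a positive mean gap as well, 0.119 ± 0.0399 (SD, n = 3), with testis-higher probes at 0.1925 and ovary-higher probes at 0.0732. A positive gap was thus not particular to early transforming gonads. The differences in gap of undifferentiated gonads and early testis from early transforming gonads were not tested. Over the 10 tests of both classes, all 5 steps of the testis-higher probes had an adjusted p of 0.0408 by the exact permutation test. Of the ovary-higher probes, the step from early to late transforming gonads (0.589) and that from undifferentiated gonads to early testis (-0.0983) had the same adjusted p. The ovary-higher step from adult testis to early transforming gonads (0.217) and that from late transforming gonads to adult ovary (0.181) missed the threshold, with an adjusted p of 0.0635 by the exact permutation test, as did that from early to adult testis (-0.0609, adjusted p = 0.2).

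**Figure D3:**
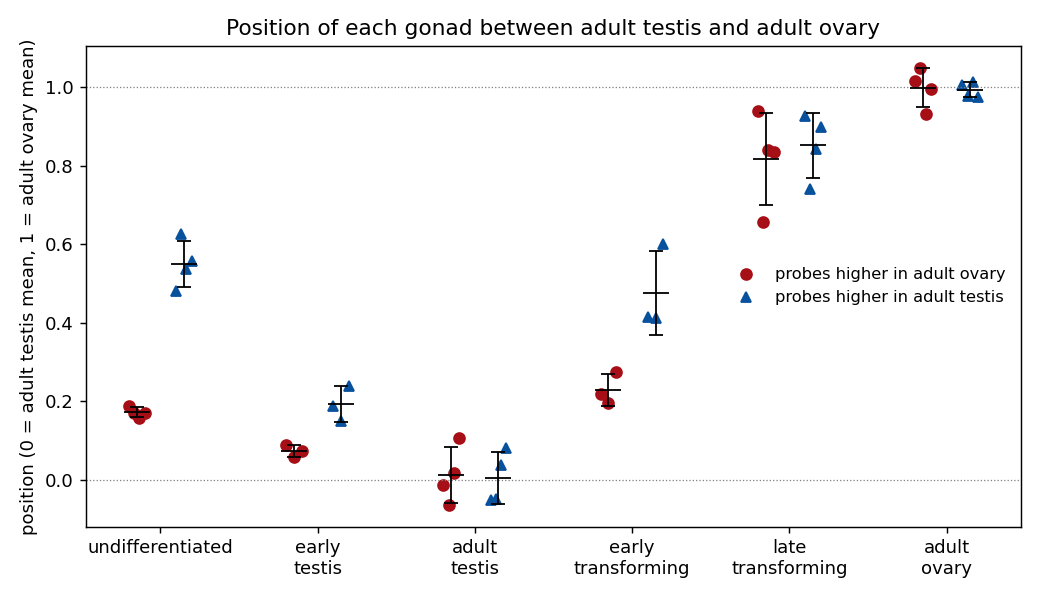
Position of each gonad between the adult testis mean (0) and the adult ovary mean (1) on the vertical axis, for the 6 groups on the horizontal axis; circles are medians over ovary-higher probes, triangles medians over testis-higher probes, and bars the group mean ± SD. In the 3 early transforming gonads the testis-higher probes (mean 0.475) lie above the ovary-higher probes (mean 0.229), and the late transforming gonads lie near the adult ovaries for both classes.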

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

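The test for admixed ovarian tissue, the further scalings on bright probes and the ovary-higher position of early transforming replicate 3 were chosen only after the result was seen, and the other tests in this part were set out before their results.

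In adult testis replicate 1 the level of SBRGG_29268 was 9.6441 (log2), while the other adult testes lay between 10.88 and 10.97. In late transforming replicate 2 the level of SBRGG_01719 was 6.5958 (log2), while the other late transforming gonads lay between 8.73 and 9.15. Each had a gap to its nearest neighbour that was large against the range of its group. The check covered 31 groups of 4 values, namely the share of probes above background, the positions and the levels of the 4 transcripts, and chance gives about 1.6 such values. Groups of 3 were not checked, and a value in a widely spread group, such as 5.12 for SBRGG_01719 in adult testis replicate 4, can miss this criterion.

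Grouping the arrays by their labels gave more calls than any other split of the same arrays in all 6 comparisons. With 35 splits no share below 1 in 35 is possible, and the 6 comparisons were not corrected together. The splits therefore cannot exclude chance for each comparison. In each, only 1 of 35 splits reached the real count, the real one itself. The real and highest other counts were 23370 and 77 for adult ovary against adult testis, 7197 and 2002 for adult testis against early testis, and 9034 and 505 for adult ovary against late transforming gonads. They were 14729 and 11487 for early testis against undifferentiated gonads, where the other split moved undifferentiated replicate 1 to the early testes. They were 17498 and 11535 for early transforming gonads against adult testis, where it moved adult testis replicate 4 to the transforming gonads. They were 19442 and 17695 for late against early transforming gonads, where it moved late transforming replicate 2 to the early group. Each of these 3 splits leaves the remaining arrays as labelled and none follows a slide.

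Testis-higher transcripts lay further towards the ovary than ovary-higher transcripts in early transforming gonads, with a mean gap of 0.246 in position. A background floor was argued against, because on probes well above background on all 8 adult arrays the gap was 0.5263 on average. Array scaling changed its size but the lowest gap of any array was 0.0588, with means of 0.460 under median scaling, 0.168 ± 0.123 (SD, n = 3) under quantile normalization and 0.163 in the authors' matrix, where the bright probes gave 0.264 and at least 0.149. A mixture of adult ovarian tissue with adult testis would raise low transcripts further than it lowers high ones on a log scale, yet the lowest gap was 0.1967 in the opposite sense. What underlies the gap stays open. Undifferentiated gonads had a wider mean gap in the main scaling (0.378 ± 0.0663, SD, n = 4), a difference that was not tested. Early testis had a smaller positive one (0.119 ± 0.0399, SD, n = 3), also not tested. The order of loss and gain, a changed mix of cell types and any difference in age were not tested either.

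The change from adult testis to early transforming gonads resembled the change from early testis back to undifferentiated gonads, with r = 0.692 and Spearman's rho = 0.588 across 35868 probes and no shared array. Of the probes called in both, 9122 changed the same way and 474 the opposite way, where independent lists would share 1808 higher and 1785 lower. Probes near background are argued against as the cause, since probes well above background on all arrays gave r = 0.7217, and so is the slide, since differences taken on separate slides gave r = 0.5868. The resemblance did not rest on early transforming replicate 3, without which r was 0.6276. Both changes start from a testis at stage M3, and how much of r reflects a general move away from testis was not tested. Early testis minus undifferentiated correlated at r = -0.431 with adult ovary minus adult testis. Of the probes called in both of these, 7056 changed in opposite directions and 2887 in the same. What the groups have in common, such as their germ cell content, was not tested because the transcripts have no gene names.

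Early transforming replicate 3, whose nearest array was undifferentiated replicate 3 (r = 0.891), was the dimmest of its group. Of its probes 46.9% were well above background, against 53.6% and 58.7% on replicates 1 and 2. Its 75th percentile signal was 109.5 against 140.6 and 173.6. It held 314 probes well above background and at least 4-fold above every other array, against at most 64 on any other array. This argues against low signal as the only reason it stood apart, but low signal on its other probes was not tested. On the line from the other early transforming gonads (0) to the undifferentiated gonads (1) it stood at 0.514, below the undifferentiated gonads at 0.553 to 1.23, which did not decide whether it was an undifferentiated gonad under a wrong label. Its testis-higher probes stood at 0.599, inside the undifferentiated range of 0.481 to 0.625 and apart from the other early transforming gonads (0.414 and 0.412), as a wrong label would give. Its ovary-higher probes stood at 0.274 against 0.158 to 0.189 in the undifferentiated gonads (mean 0.172, SD 0.0128, n = 4). They lay above all of them under 9 of 9 processing settings, by over 3 SD in 7. The exceptions were normexp and no filter on dim probes. These settings are not separate checks, since some gave the same or nearly the same values. The position also lay above the other early transforming gonads (0.218 and 0.1945). It set the array apart from both groups and so cannot decide between them. An undifferentiated gonad under a wrong label thus stays open. An unusual early transforming gonad, a mixed sample or another wrong label stays open too and was not tested.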

How the results depend on the processing

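The alternatives in this part were fixed before the data were examined. No difference in position and no fold of a named transcript changed sign under the alternatives run for it, whereas the direction that held more calls did change with the scaling. The counts of called probes stayed within 1.5 times the main count under median scaling, quantile normalization, normexp, no filter on dim probes, saturated or outlier spots treated otherwise, the authors' matrix values, the slide as a block, fits of the compared groups alone, no intensity trend and a 2-fold threshold. The 4 named transcripts passed the limma threshold under every alternative that tested them. Testing only the 13582 probes well above background on all arrays left 9566 calls for adult ovary against adult testis, 5869 for early testis against undifferentiated, 3343 for adult against early testis, 6983 for early transforming against adult testis, 8189 for late against early transforming and 4561 for adult ovary against late transforming, because fewer probes were tested. The overlap of the late against early transforming calls with the adult calls was then 5354, where independent lists would share 3286.

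Leaving out 1 array at a time gave 3229 to 6684 calls for adult against early testis (lowest without early testis replicate 3, 4097 without adult testis replicate 2, 4645 without early testis replicate 1), and the cause was not tested. On the testis to ovary axis it gave 0.478 to 0.560 for late against early transforming, 0.274 to 0.337 for early transforming against adult testis, 0.116 to 0.199 for adult ovary against late transforming and -0.179 to -0.150 for early testis against undifferentiated. For late against early transforming, early transforming against adult testis and early testis against undifferentiated the adjusted p was then 0.0667 to 0.1, because 2 arrays against 4 or 3 against 3 allow no p under 0.0667. For adult ovary against late transforming it was 0.0571 without any 1 adult ovary array, and the cause was not tested. For adult ovary against late transforming, normexp gave 0.0986 with an adjusted p of 0.0714, against 0.0357 under the other processing settings, and the cause was not tested.

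Median scaling moved the median log2 fold of all tested probes by 0.26 for adult ovary against adult testis, 0.19 for early testis against undifferentiated, -0.20 for early transforming against adult testis, 0.24 for late against early transforming and 0.22 for adult ovary against late transforming. The share of calls higher in the first group crossed 50% under at least 1 scaling in all 6 comparisons. It was 52.4% for adult ovary against adult testis, 49.9% after quantile normalization, 57.8% with median scaling and 71.2% on probes above background throughout. For adult against early testis it was 52.0%, 40.0% after quantile normalization, 39.6% in the authors' matrix and 66.9% with normexp. For early testis against undifferentiated it was 49.6%, 59.2% with median scaling, 51.6% after quantile normalization, 35.8% with normexp and 36.3% with no filter. For early transforming against adult testis it was 49.9%, 42.98% with median scaling and 52.9% after quantile normalization. For late against early transforming it was 51.1%, 59.2% with median scaling, 47.4% after quantile normalization and 66.4% on probes above background throughout. For adult ovary against late transforming it was 54.6%, 67.4% with median scaling, 49.95% after quantile normalization, 70.05% with normexp and 70.4% on probes above background throughout.

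No paired analysis was possible because the replicate numbers were given in accession order and pair no samples. The gene list tests and the choice among probes of a gene were not run because no probe had a gene name. Dim probes leave the folds near background of the named transcripts uncertain, and those of 3 are given against a floor.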

Other observations

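The counts of group-specific transcripts and of probes above background were chosen only after the data were seen.

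Adult ovary, adult testis and undifferentiated gonads had the most group-specific transcripts. Adult ovary was at least 2-fold higher than each of the other 5 groups in 2055 probes and lower than each in 1913 (limma, adjusted p under 0.05 in all 5 contrasts). Adult testis was higher than each in 1753 and lower in 1047, and undifferentiated gonads in 1487 and 960. Late transforming gonads had 476 such higher and 418 lower probes, while early transforming gonads had 92 and 34 and early testis 88 and 53, in groups of 3 arrays. On probes well above background on all arrays, the higher and lower counts were 1177 and 453 for adult ovary, 535 and 557 for adult testis, 450 and 401 for undifferentiated, 146 and 163 for late transforming, 21 and 12 for early transforming and 16 and 21 for early testis. The order of adult ovary and adult testis by lower counts was thus reversed on these probes.

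Early transforming gonads were not only intermediate between the adult sexes. A total of 4297 probes were higher in them than in both adult groups and 3096 lower than in both. Most of the higher probes were shared with undifferentiated gonads. Of the 4297, 3419 were among the 6282 probes above both adult groups in undifferentiated gonads, where independent lists would share 753. In late transforming gonads 1372 probes were higher and 1329 lower than in both adult groups, and 713 probes were higher than both adults at both stages. Against other groups, early transforming gonads differed in 5725 probes from undifferentiated gonads and in 5713 from early testis, fewer than the 17498 from adult testis and the 22576 from adult ovary.

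The share of probes well above background was 43.2% ± 2.47 (SD, n = 4) in adult ovary and 55.9% ± 2.96 (SD, n = 4) in adult testis, and every ovary array lay below every testis array. The exact two-sided permutation test gave p = 0.0286 and an adjusted p of 0.171 over 6 comparisons, so the difference fails the correction. Every adult ovary array also had a lower 75th percentile signal than every adult testis array, and detection can depend on brightness. The share was 57.3% ± 3.18 (SD, n = 3) in early testis and 49.2% ± 4.96 (SD, n = 4) in undifferentiated gonads.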
